A study of Mus musculus with 14 samples.

How the data were processed

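Gene counts were analysed for 14 libraries of mouse dorsal skin epithelium, 7 from the MAdCAM-1 positive, placode-enriched fraction and 7 from the MAdCAM-1 negative fraction, called IFE. Per the labels' protocols, Dispase II separated the epithelium from the mesenchyme, TrypLE gave single cells, live cells were sorted into a lysis reagent, and total RNA was made into libraries with the Ovation SoLo kit. The deposited table holds raw read counts per Ensembl gene, which the authors did not normalize as far as the whole-number values show. Per the submitters' processing notes, bcl2fastq (2.17.1.14), Trimmomatic, FastQC, MultiQC, STAR (listed as 1.5) and HTSeq were used with the builds GRCm38 and mm10. The annotation release, the strand setting and the treatment of duplicate reads or molecular identifiers are not given in the sources used here. Amplified reads without molecular identifiers are not independent molecules, and genes that overlap on opposite strands may share reads. Of the 127 genes named by the rule below, 30 overlap a gene on the opposite strand, among them Shh, Axin2, Krt10, Ctnnb1, Pmel and mt-Nd6.

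Gene symbols and coordinates came from GENCODE release M21 (GRCm38). Of 26252 gene identifiers, 25949 matched, and the 303 others held 0.44% of all counts. The smallest total of any gene over the 14 libraries was 2, and 0 columns were left unused. Library totals lay between 23.8 and 49.5 mega counts, which is only part of what limits the precision of each value. Each library was counted as its own sample, as the labels give it.

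The pairs come from the labels: the design text names 7 pairs of populations, the title codes are shared by 2 libraries each, and a sample pools embryos of a litter. The pair was therefore a block in the design. Deviations from the fraction means correlated by 0.055 on average between libraries of a pair (-0.132 to 0.195 across genes, over 0.1 in 2 pairs; exact permutation p = 0.17 over 5040 pairings, two-sided). A score of sex-linked transcripts, Xist minus the mean of 4 Y-linked genes in log2 CPM, correlated between the libraries of a pair with Pearson r = 0.996 (exact permutation p = 0.000397) and a Spearman correlation of 0.964 (exact permutation p = 0.00278). Without the 2 pairs farthest from the median the Pearson r was 0.988. The labels do not say whether the 3 pairs whose codes start with 27-7 share a litter or a day, so p-values measure the spread between these pools.

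Counts were analysed with edgeR 4.0.16 (limma 3.58.1, R 4.3.3; Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 for tables, matplotlib 3.10.9 for figures). Genes with low counts were removed with filterByExpr, which left 15382 genes and removed 10870, libraries were scaled by TMM, and robust quasi-likelihood F tests compared the fractions with the pair as a block. P-values were adjusted by the Benjamini-Hochberg method at 0.05. The common biological coefficient of variation was 0.216. Fold changes are log2 values of placode-enriched over IFE with a prior count of 0.125, and the standard errors are approximate, the unshrunk coefficient divided by the square root of F. CPM use TMM-scaled library sizes. Differences per pair used a prior count of 2.

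The design, the tests and 32 gene lists with 739 members, of which 719 were found in the table, were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 29 lists with 2 or more tested genes. With this setting 12 lists passed. With an estimated correlation 9 of them held, namely the placode, Hedgehog, Eda, BMP, FGF, suprabasal, junction, matrix and melanoblast lists. The rotation test fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, was run as an alternative. Summed CPM of the 9 lists for other cell types and 2 for RNA quality were compared by exact two-sided sign-flip tests over 7 pairs, adjusted over 11 lists. Genes were named by a fixed rule: Madcam1 as a check of the sort, 19 chosen names, the 12 highest and 12 lowest genes past the threshold with the same sign in 7 pairs and a mean of at least 10 CPM in the higher fraction, and up to 4 passing members of each list, or the member with the smallest p where none passed. Predicted and numbered gene models were left out of the highest and lowest genes. Not every gene that the rule gives is named in the text. Other list members are named where a count or sum rests on them.

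Alternatives were no pair block, DESeq2 size factors, upper-quartile scaling, library size only, no filter, a stricter filter of 1 CPM in 7 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersion, mitochondrial genes left out, each pair left out, each set of pairs alone and a threshold of 0.01. A covariate for structural noncoding RNA and the removal of those genes were chosen after seeing the data. The methods were tested on simulated data with 200 changed genes among 15382. The simulation was rewritten once, and the values are those of the later version. It drew its means from a fit to the real counts without the fractions, and its dispersions from a fit with them. The real data gave 4786 calls, far more than 200 genes, so the rates below belong to a setting with fewer changes. For the comparison of the fractions, edgeR recovered 56% of genes changed 1.5-fold, 72% at 2-fold, 92% at 4-fold and 96% at 8-fold, and 3.1% of its 163 calls were unchanged genes. For the interaction with the title code it recovered 4%, 54%, 74% and 76% at these sizes. For DESeq2, 14.9% of 194 calls were unchanged genes.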

Results

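RNA was sequenced from dorsal skin epithelium of wild-type C57BL/6JOlaHsd mouse embryos at E14.5, a stage at which placodes, the local thickenings that give rise to hair follicles, lie within interfollicular epithelium (IFE). Epithelial cells were sorted by an antibody against the cell adhesion molecule MAdCAM-1 into a positive fraction, called placode-enriched, and a negative fraction, called IFE. The 14 libraries formed 7 pairs of both fractions, and each library came from the pooled epithelium of 3 to 4 littermate embryos. Total counts per library, in mega counts (M), lay between 23.8 M and 49.5 M, with means of 32.8 ± 8.42 M in the placode-enriched and 33.7 ± 4.92 M in the IFE libraries (SD, n = 7 each). Each library had counts in 18185 to 21670 of the 26252 genes listed. The first principal component of log2 CPM held 46.7% of the variance and separated the 2 populations, as shown in the plot of library scores.

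**Figure D1:**
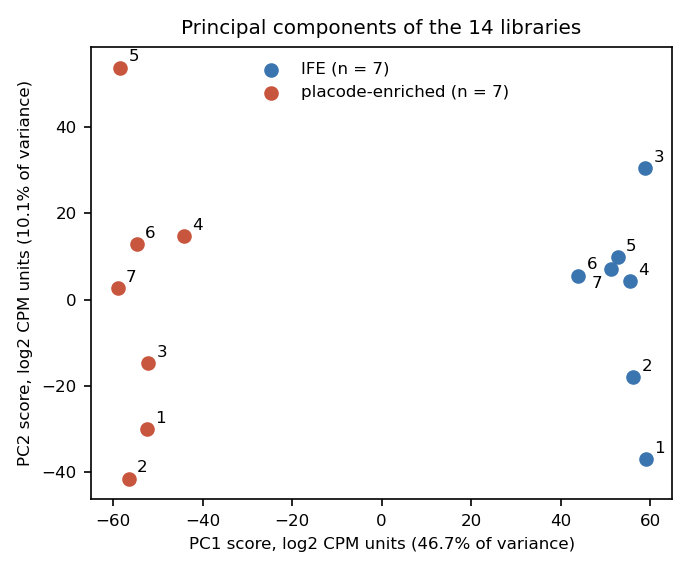
Scores of the 14 libraries on the first and second principal components of log2 CPM, in log2 CPM units, with replicate numbers beside the points. On the first component, 46.7% of the variance, the placode-enriched libraries lie between -59.01 and -44.25 and the IFE libraries between 44 and 59.01.

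The comparison of both fractions asked which genes distinguish cells of the early hair follicle from those of the epidermis around it. Genes of the hair placode were higher in the placode-enriched cells, and genes of differentiating epidermis and of pigment cells were lower. Shh, the ligand of the Hedgehog pathway (ENSMUSG00000002633; GRCm38 chromosome 5, 28456815 to 28467256, minus strand), stood at 105 ± 23.4 CPM in placode-enriched and 2.02 ± 0.767 CPM in IFE libraries (mean ± SD, n = 7 each). Its log2 fold change was 5.74 ± 0.17 (approximate SE; edgeR adjusted p = 8.75e-11). Krt10, a keratin of suprabasal epidermis (ENSMUSG00000019761; chromosome 11, 99385254 to 99389364, minus strand), stood at 107 ± 35.6 CPM in placode-enriched and 1490 ± 266 CPM in IFE libraries, a log2 fold change of -3.84 ± 0.10 (edgeR adjusted p = 4.12e-11). Madcam1, which encodes the protein used for the sort (ENSMUSG00000020310; chromosome 10, 79664559 to 79668537, plus strand), stood at 47.9 ± 12.1 CPM against 0.561 ± 0.367 CPM. Its log2 fold change of 6.45 ± 0.23 checks the sort and is not a finding. The plot of CPM by library shows the values of 12 genes, these among them.

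**Figure D2:**
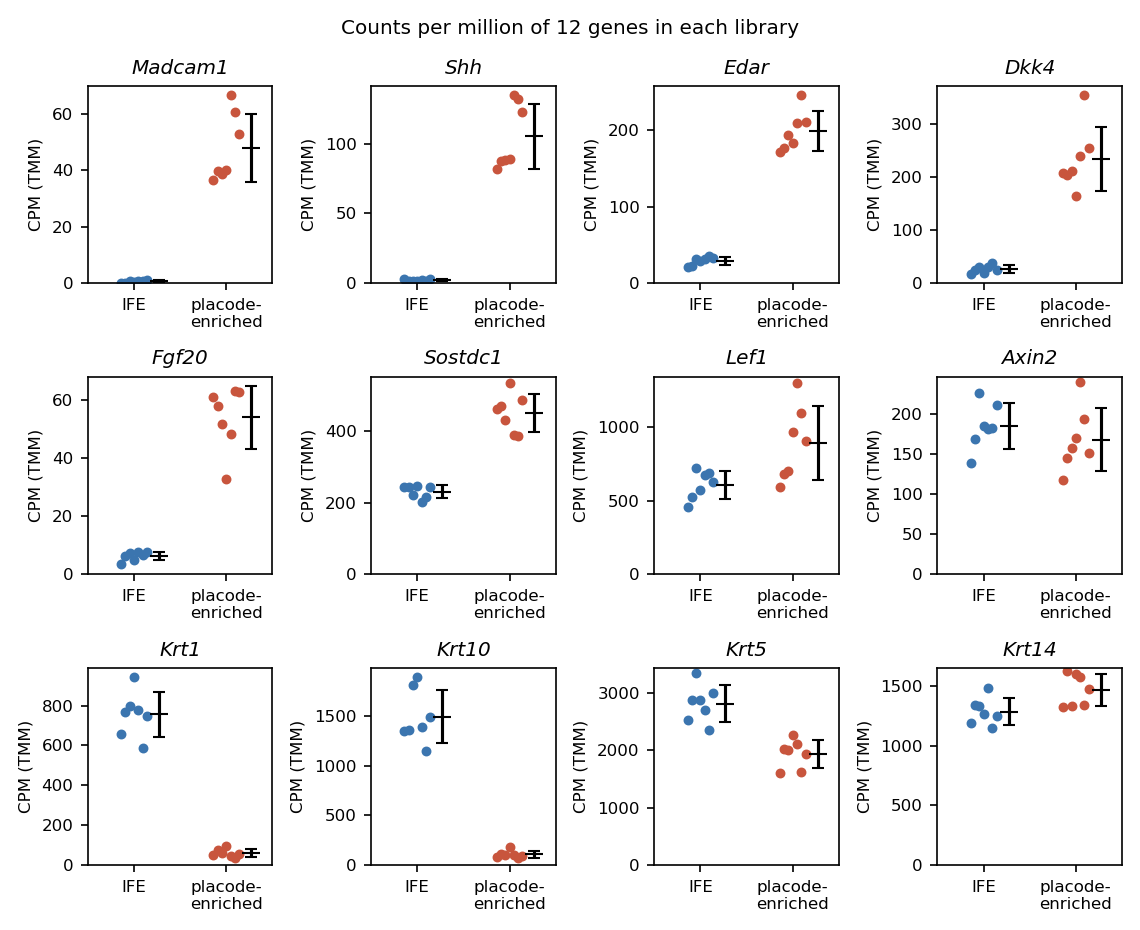
CPM with TMM-scaled library sizes of 12 genes in the 7 IFE (blue) and 7 placode-enriched (red) libraries; each point is a library, and the black marks give mean ± SD. For Shh, Edar and Dkk4 every placode-enriched library lies above every IFE library, for Krt1 and Krt10 every one lies below, and for Axin2 the libraries overlap.

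Among the 12 genes highest in the placode-enriched cells were Wif1, a secreted Wnt inhibitor, at a log2 fold change of 5.36 ± 0.18, and Nrp2, a semaphorin and VEGF receptor, at 5.20 ± 0.17. Bdnf, a neurotrophin, followed at 4.92 ± 0.21, Sp5, a transcription factor downstream of Wnt signalling, at 4.91 ± 0.34, and Lhx2, a LIM-homeodomain transcription factor, at 4.84 ± 0.29. Adamts15 (6.08 ± 0.55), Slc14a1 (5.47 ± 0.40), Prokr2 (5.18 ± 0.19), Steap4 (4.76 ± 0.36) and Mical2 (4.72 ± 0.10) were also among them. The 12 lowest held the pigment-cell genes Dct (-6.07 ± 0.43) and Tyr (-5.38 ± 0.40), with Zeb2 (-5.63 ± 0.31) and the cystine transporter Slc7a11 (-4.68 ± 0.20). Genes of the cornifying epidermis were among the lowest too, such as the desmosomal cadherin Dsc1 (-4.52 ± 0.23), the transglutaminase Tgm3 (-4.50 ± 0.20) and the lipid enzyme Pnpla1 (-4.86 ± 0.25). Serpinb12 stood at -4.76 ± 0.22, Pla2g4f at -4.86 ± 0.46, Cubn at -4.92 ± 0.29 and Ano7 at -4.75 ± 0.33. Serpinb3a (-5.32 ± 0.42) is uncertain, because it has near-identical neighbours among which reads can be split. Each of these genes changed the same way in 7 of 7 pairs.

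Of 15382 genes tested, 4786 (31.1%) differed between the fractions at an adjusted p under 0.05 (edgeR quasi-likelihood test with the pair as a block). Of these, 2384 were higher and 2402 lower in the placode-enriched cells, and 1631 differed at least 2-fold, 878 higher and 753 lower. Of all 15382 genes tested, 4070 changed the same way in 7 of 7 pairs, where chance gives 1.56% of genes. The count fell to 2331 genes (1226 higher, 1105 lower) in the 3 pairs whose title codes start with 27-7 and to 3087 (1547 higher, 1540 lower) in the 4 other pairs, each analysed alone.

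Markers of the hair placode were higher as a group. Of 20 tested, 19 passed and were higher, and 1 did not pass (19 adjusted over the list alone), with a median log2 fold change of 2.32 (camera adjusted p = 1.35e-66). Edar, the ectodysplasin receptor, stood at 199 ± 26 against 28.9 ± 5.2 CPM, a log2 fold change of 2.79 ± 0.07. Trps1 (3.54 ± 0.08), Ltb (4.52 ± 0.13) and the transcription factor Foxi3 (3.35 ± 0.16) rose as well, and Sostdc1, an inhibitor of BMP and Wnt signalling, rose by 0.97 ± 0.06. Wnt10a was the member that did not pass, at 42.8 against 50.8 CPM (log2 -0.24). Several placode markers are also members of the pathway lists below, so those lists are not independent of this one.

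Genes of the Eda, Hedgehog and FGF pathways were higher in the placode-enriched cells. In the Eda and NF-kB list, 14 of 20 tested members were higher, 2 lower and 4 did not pass (14 and 3 adjusted over the list alone), with a mean of 1.15 (camera adjusted p = 5.66e-17). Tnfaip3, a feedback inhibitor of NF-kB, rose by 2.76 ± 0.12, whereas the ligand gene Eda fell, with a log2 fold change of -0.90 ± 0.09. In the Hedgehog list, 9 of 13 were higher, 2 lower and 2 did not pass (10 and 2 adjusted over the list alone; median 0.62; camera adjusted p = 2.53e-10). The receptor and target genes Ptch1 (1.59 ± 0.08) and Gli1 (1.58 ± 0.11) rose with Bcl2 (1.61 ± 0.08), and the co-receptor gene Cdon fell (-0.71 ± 0.07). In the FGF and ERK list, 12 of 23 were higher, 6 lower and 5 did not pass (13 and 7 adjusted over the list alone; median 0.40; camera adjusted p = 1.82e-12). Fgf20 (3.11 ± 0.15), Fgfr1 (2.67 ± 0.09), the ERK feedback phosphatase gene Dusp6 (2.85 ± 0.08) and Etv4 (3.06 ± 0.11) rose, and Egfr fell (-0.52 ± 0.07).

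In the BMP and TGF-beta list, 11 of 30 were higher, 7 lower and 12 did not pass (13 and 7 adjusted over the list alone; median 0.14; camera adjusted p = 0.000698). Bmp2 (1.70 ± 0.07) and Tgfb2 (3.49 ± 0.15) rose, and Id2, a common BMP target, fell (-1.07 ± 0.12). Of the Wnt/beta-catenin targets, 12 of 21 were higher, 2 lower and 7 did not pass (12 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 4.23e-09). This call was lost with adjusted p = 0.0754 with an estimated correlation. Dkk4 (3.16 ± 0.10) and Wif1, both secreted Wnt inhibitors, rose together with Lgr6 (2.45 ± 0.08), and Lef1, a transcriptional partner of beta-catenin, rose by 0.52 ± 0.10 in 6 of 7 pairs. Nkd2, an intracellular Wnt antagonist, fell (-1.65 ± 0.22). Axin2, a broadly used Wnt feedback target, stood at 167 ± 39.2 CPM in placode-enriched and 184 ± 28.4 CPM in IFE libraries, a log2 fold change of -0.16 ± 0.10 (edgeR adjusted p = 0.282). Without replicate 5 the Axin2 value was -0.25 (edgeR adjusted p = 0.0391).

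Among Wnt ligands, receptors and secreted inhibitors, 16 of 36 were higher, 7 lower and 13 did not pass (16 and 8 adjusted over the list alone; median 0.22), and the list missed the threshold (camera adjusted p = 0.0521). It passed without the pair block (0.0325), with library size only (0.0456), with the stricter filter (0.0466) and without replicate 2, 3 or 7 (0.037, 0.0361 and 0.0369). An estimated correlation gave this list a camera adjusted p of 0.406. Wnt10b (1.60 ± 0.12), Lrp4 (1.91 ± 0.08) and Dkk3 (2.75 ± 0.24) rose and Wnt16 fell (-1.43 ± 0.11). In the Notch list, 3 of 18 were higher, 9 lower and 6 did not pass (4 and 9 adjusted over the list alone; median -0.29), with a camera adjusted p of 0.0518. This list passed with library size only (0.0302), with the stricter filter (0.0466) and without replicate 5 (0.00835). Its camera adjusted p was 0.403 with an estimated correlation. Notch3 (-2.32 ± 0.11), the Notch target Nrarp (-1.07 ± 0.08) and the ligand gene Jag1 (-0.75 ± 0.06) fell, and Lfng, which modifies Notch receptors, rose (0.90 ± 0.09).

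Genes of the differentiating epidermis were lower in the placode-enriched cells without exception among those tested. All 23 tested members of the suprabasal list fell (23 adjusted over the list alone), with a median log2 fold change of -3.59 (camera adjusted p = 8.44e-69). Krt1 stood at 58.6 ± 19.8 against 755 ± 112 CPM (-3.74 ± 0.11), and Grhl1, a transcription factor of epidermal differentiation, fell by 2.48 ± 0.07 on the log2 scale. Of 35 genes of cell-cell junctions, 22 were lower, 6 higher and 7 did not pass (22 and 6 adjusted over the list alone; median -0.47; camera adjusted p = 8.94e-09). The desmosomal genes Dsc3 (-2.01 ± 0.08), Pkp1 (-1.82 ± 0.07) and Perp (-1.35 ± 0.07) fell, whereas Ctnnb1, which encodes beta-catenin, rose (1.30 ± 0.08). Levels in these and the other lists are averages over each fraction. A different share of suprabasal cells cannot be told apart from a change within a cell layer. Of 9 periderm genes, 6 were lower and 3 higher (6 and 3 adjusted over the list alone; median -2.21), and the list missed the threshold (camera adjusted p = 0.0912), which it passed without replicate 1 (0.0457) or 4 (0.0359). Its camera adjusted p was 0.245 with an estimated correlation. Rhov (-2.17 ± 0.11), Gabrp (-2.76 ± 0.20) and Sprr1a (-3.08 ± 0.24) fell, and Krt17, a keratin also made by placodes, rose (2.28 ± 0.07).

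Basal epidermal genes went both ways. Of 19 tested, 6 were higher, 7 lower and 6 did not pass (8 and 7 adjusted over the list alone), with a median of 0.08, a mean of -0.08 and a downward test (camera adjusted p = 0.969). Krt5 (-0.54 ± 0.07), Krt15 (-0.90 ± 0.07) and Igfbp3 (-1.43 ± 0.19) fell. Krt14, the partner of Krt5 in basal cells, stood at 1468 ± 134 against 1285 ± 111 CPM, a log2 fold change of 0.19 ± 0.07 (edgeR adjusted p = 0.0397). The Krt14 call was lost without the pair block (0.0851) and without replicate 1, 2, 4, 6 or 7 (0.0841, 0.0981, 0.12, 0.106 and 0.0864).

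Few genes of S phase or of G2 and M phase passed, whereas cell cycle inhibitors went both ways. Of 30 S phase genes, 5 were lower and 25 did not pass (3 lower adjusted over the list alone; median -0.06; camera adjusted p = 0.443). Ccne2 (-0.56 ± 0.07), Prim1 (-0.31 ± 0.07) and Ccne1 (-0.36 ± 0.09) were among those that fell. Of 30 genes of G2 and M phase, 6 were higher and 24 did not pass (5 higher adjusted over the list alone; median 0.18; camera adjusted p = 0.094, or 0.0186 without replicate 5). An estimated correlation gave this list a camera adjusted p of 0.66. Kif2c (0.45 ± 0.07), Nusap1 (0.33 ± 0.08) and Kif20a (0.26 ± 0.07) rose. Mki67, a proliferation marker, stood at 2216 ± 140 against 2093 ± 130 CPM (log2 0.08 ± 0.07; edgeR adjusted p = 0.431). Among 14 cell cycle inhibitors, 4 were higher, 6 lower and 4 did not pass (4 and 6 adjusted over the list alone; median -0.10; camera adjusted p = 0.576). Cdkn1a fell from 37.3 ± 8.23 to 7.26 ± 1.58 CPM (-2.36 ± 0.11), Cdkn1c (-0.54 ± 0.07) and Rb1 (-0.51 ± 0.11) fell, and Gadd45g rose (1.43 ± 0.13).

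Of 31 basement membrane and matrix genes, 15 were higher, 5 lower and 11 did not pass (15 and 5 adjusted over the list alone; median 0.43; camera adjusted p = 1.37e-08). Fn1, which encodes fibronectin, stood at 605 ± 118 against 53.5 ± 8.12 CPM (3.49 ± 0.07), Frem1 at 467 ± 42.8 against 26.4 ± 5.44 CPM (4.17 ± 0.09), and Vwa2 rose by 1.44 ± 0.08, whereas Col4a6 fell (-0.59 ± 0.08). Of 52 guidance genes of the semaphorin, ephrin, slit and netrin families, 27 were higher, 7 lower and 18 did not pass (31 and 7 adjusted over the list alone; median 0.40; camera adjusted p = 5.89e-10). That call was lost, at adjusted p = 0.0693, with an estimated correlation. Sema6d (1.20 ± 0.06) and Robo2 (2.15 ± 0.11) rose and Plxna2 fell (-0.70 ± 0.06). Of 37 developmental transcription factors, 18 were higher, 10 lower and 9 did not pass (20 and 10 adjusted over the list alone; median 0.17; camera adjusted p = 1.37e-05), a call lost at adjusted p = 0.317 with an estimated correlation. Runx1 rose (2.80 ± 0.09) and Dlx5 fell (-2.79 ± 0.16). Among 29 actomyosin and focal adhesion genes, 7 were higher, 11 lower and 11 did not pass (7 and 11 adjusted over the list alone), with a median of -0.02, a mean of -0.05 and an upward test (camera adjusted p = 0.995). Amotl2 (-0.89 ± 0.07), Vcl (-0.70 ± 0.06) and Acta2 (-2.65 ± 0.34) fell and Ccn2 rose (2.15 ± 0.08).

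Of 22 genes of cholesterol synthesis, 8 were lower and 14 did not pass (10 lower adjusted over the list alone; median -0.20), and the list missed the threshold (camera adjusted p = 0.0518). It passed without the pair block (0.0485), with library size only (0.0487) and without replicate 3 (0.0275) or 7 (0.0459). An estimated correlation gave this list a camera adjusted p of 0.113. Mvk (-0.90 ± 0.11) and Dhcr7 (-0.55 ± 0.09) fell. Of 22 glycolysis genes, 2 were higher, 8 lower and 12 did not pass (3 and 8 adjusted over the list alone; median -0.15; camera adjusted p = 0.0912). Slc2a3 (-1.38 ± 0.09), Ldha (-0.43 ± 0.06) and Aldoc (-0.91 ± 0.15) fell, and the lactate transporter gene Slc16a3 rose (1.25 ± 0.27).

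Markers of other cell types moved with the fractions in part. All 9 tested melanoblast markers were lower in the placode-enriched cells (9 adjusted over the list alone; median -4.43; camera adjusted p = 2.72e-19), among them Pmel (-4.30 ± 0.17), Ednrb (-4.43 ± 0.22) and Kit (-3.92 ± 0.22). The summed level of all markers of that list in the table was 11.9 ± 2.58 CPM in placode-enriched and 178 ± 37.6 CPM in IFE libraries (SD, n = 7 each), lower in 7 of 7 pairs. The exact two-sided sign-flip p was 0.0156, the smallest that 7 pairs allow, and 0.0572 after adjustment over 11 lists. Markers of Schwann cells and neurons were lower by 0.74 on the log2 scale in the sum over all markers in the table (92.7 ± 9.89 against 154 ± 5.05 CPM, 7 of 7 pairs, same exact p), with 3 of 5 tested members lower and 2 not passing (4 lower adjusted over the list alone; camera adjusted p = 0.053). That list passed without the pair block (0.0262) and without replicate 1, 3 or 7 (0.0178, 0.0147 and 0.046). Its camera adjusted p was 0.151 with an estimated correlation. Erbb3 (-0.70 ± 0.07), Tubb3 (-3.46 ± 0.72) and Fabp7 fell, the last to a mean of 0.0402 CPM.

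Of 12 tested genes associated with dermal fibroblasts, 5 were higher, 4 lower and 3 did not pass (5 and 4 adjusted over the list alone; median 0.21; camera adjusted p = 0.248). Dcn (498 ± 79.2 against 258 ± 24.2 CPM; 0.94 ± 0.10), Fbn1 (0.78 ± 0.08) and Col1a2 (1.25 ± 0.09) rose, whereas Vim fell (-1.17 ± 0.10). The sum over all genes of that list in the table was 1870 ± 231 against 1450 ± 111 CPM, higher in 7 of 7 pairs (exact sign-flip p = 0.0156, adjusted 0.0572), or in 6 of 7 with raw library sizes (exact sign-flip p = 0.0312). Postn (1042 ± 192 against 745 ± 82.6 CPM) and Dcn carried this rise, while Col5a1, Vim, Col1a1, Col3a1, Col6a1 and Col6a3 had lower mean CPM in the placode-enriched libraries.

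The remaining lists held few tested genes. In the endothelial list 2 of 3 were higher (2 adjusted over the list alone), with a camera adjusted p of 0.415. Pecam1 (2.15 ± 0.44) stood at 1.83 against 0.493 CPM and Ramp2 (1.73 ± 0.47) at 1.6 against 0.609 CPM. The most abundant member, Egfl7, was at 2.79 against 3.47 CPM, and Cdh5 and Emcn were near 0. In the myeloid list Aif1 was higher (2.53 ± 0.50), Cx3cr1 lower (-1.78 ± 0.28) and 2 of 4 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.972). Cx3cr1 overlaps 5 other genes, and the myeloid genes Ptprc, Csf1r and Tyrobp were near 0 in both fractions. In the Merkel cell list Sox2 was higher (3.58 ± 0.41) and Piezo2 lower (-0.58 ± 0.17; 1 and 1 adjusted over the list alone; camera adjusted p = 0.443). The Piezo2 call was lost without replicate 7 (0.0658). The other members of that list had too few counts to be tested. Atoh1 stood at 1.03 against 0.0391 CPM. Isl1, Insm1, Pou4f3, Nefm and Krt20 also had higher mean CPM in the placode-enriched libraries, and Rab3c had lower. Lck, the single T cell gene tested, was at 0.46 ± 0.15 (1 higher adjusted over the list alone), a call lost without replicate 1, 2, 4, 5 or 6 (0.0724, 0.0715, 0.0587, 0.0767 and 0.0884). In placode-enriched libraries Lck held 16.2 of the 16.3 CPM of the T cell sum. The T cell genes Cd3e, Cd3g and Cd3d were near 0 in both fractions. Mylpf, the single muscle gene tested, was at -0.33 ± 0.37 (edgeR adjusted p = 0.572), and 0 erythroid genes had enough counts to be tested.

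**Figure D3:**
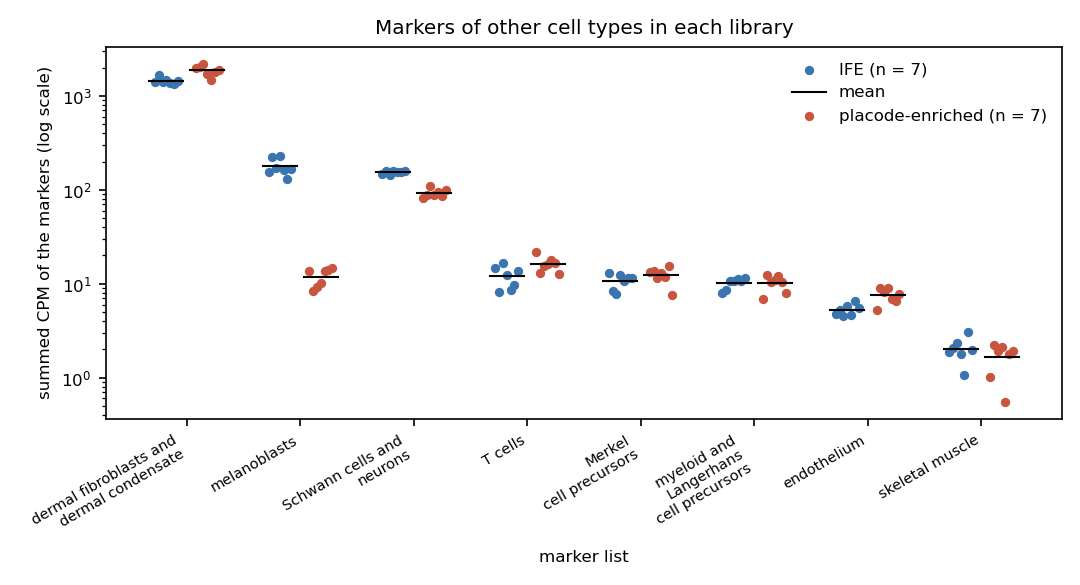
Summed CPM (log scale, TMM-scaled library sizes) of the markers of 8 other cell types in the 7 IFE (blue) and 7 placode-enriched (red) libraries; bars are means. The melanoblast sum averages 178 CPM in IFE and 11.9 CPM in placode-enriched libraries, and the dermal sum 1450 and 1870 CPM.

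Among measures of RNA quality, mitochondrially encoded genes took 6.57 ± 1.01% of counts in placode-enriched and 6.56 ± 0.78% in IFE libraries, and 0 of 8 tested members passed (0 adjusted over the list alone; camera adjusted p = 0.875). The member with the smallest p, mt-Nd6, was at -0.26 ± 0.17. Structural noncoding RNAs took 4.06 ± 1.08% and 5.17 ± 1.2% of counts. Dissociation stress genes went both ways. Of 19 tested, 6 were higher, 6 lower and 7 did not pass (7 and 8 adjusted over the list alone; median -0.16; camera adjusted p = 0.379). Socs3 (2.27 ± 0.16), Ier3 (1.39 ± 0.17) and Dusp1 (0.83 ± 0.20) rose, and Fos fell (-1.72 ± 0.13).

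Because 3 of the 7 pairs share the start of their title code (27-7), the fold changes in those pairs were compared with those in the 4 other pairs. With edgeR, 0 genes passed the interaction test, and 528 of 15382 (3.43%) had an unadjusted p under 0.05. With DESeq2, 1 gene passed and 694 had an unadjusted p under 0.05. That gene, Gm38115, was named after its values were seen, and its fold change differed by -2.62 ± 0.55 on the log2 scale (DESeq2 adjusted p = 0.0298). In edgeR its difference was -2.61 ± 0.51 (adjusted p = 0.902).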

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

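The tests of the explanations for the fibroblast-associated genes were chosen only after the result was seen, as was the count of splits for the pairs starting with 27-7.

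Values per pair or per library were examined for a sample far from the other 6. Of 188 groups of 7 values, 7 held such a sample, where chance gives about 5% of groups. The paired log2 difference of Fgf20 was 4.10 in pair 1 against 2.66 to 3.24 in the others. For Krt15 it was -0.52 in pair 4 against -1.01 to -0.87, for Ccn2 2.57 in pair 4, above the 6 others, the lowest of which was 1.96, and for Kit -5.51 in pair 2 against -4.17 to -3.25. Among libraries, placode-enriched replicate 3 had 49.5 mega counts against 23.8 to 34.3 mega counts in the others. The summed level of erythroid genes was 0.231 CPM in placode-enriched replicate 4 against 0 to 0.0394 CPM. The summed level of dissociation stress genes was 2250 CPM in IFE replicate 1 against 1540 to 1770 CPM.

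Exchanging the fractions within pairs gave 64 splits of the 14 libraries that keep the pairs, and 1 of them, the real one, gave 4786 genes, whereas the highest of the others gave 0. No other split within pairs reached that count, and 1 of 64 is the smallest share that these splits can give. In the other splits the difference between the fractions adds to the spread within groups. Their count of 0 is therefore not a chance level. For the title code 27-7, 35 of 35 splits of the 7 pairs into 3 and 4 reached the real count of 0 genes, as any split must, and the highest of the others also gave 0, so this count says nothing about chance.

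The genes Dcn, Postn, Fbn1 and Col1a2, known from dermal fibroblasts, were higher in the placode-enriched cells. Dermal cells carried into that sort could bring such transcripts, along with other abundant fibroblast collagens. The summed level of Col1a1, Col3a1, Col6a1 and Col6a3 was instead lower, at 5.04 ± 0.953 against 15.1 ± 10.5 CPM (SD, n = 7 each). The mean paired log2 difference was -1.26 ± 0.37 (SE, lower in 6 of 7 pairs, exact sign-flip p = 0.0312). These 4 genes were picked with the values of the list in view, so this p-value does not test that source. Those collagens did not rise with Dcn, Postn, Fbn1 and Col1a2. In placode-enriched libraries Dcn stood at 498 CPM, Postn at 1040, Fbn1 at 34.3 and Col1a2 at 28 CPM, each above the collagen sum of 5.04 CPM. These levels argue against dermal fibroblasts carried into that sort as the main source of Dcn, Postn, Fbn1 and Col1a2. Of the other tested list members, Lum and Pdgfra did not pass, Vim and Col5a1 were lower, and Sox2 was higher at 3.28 against 0.289 CPM. Sox2 marks both dermal condensate and Merkel cell precursors, and its source was not tested. Other dermal genes of the list were too low to be tested. Of these, Twist1 (0 against 0.318 CPM), Prrx1 (0 against 0.335 CPM), Twist2 and Sox18 were lower and Dpt was higher. The Merkel cell gene Atoh1 was higher, at 1.03 against 0.0391 CPM. Levels this near 0 do not settle the source of Sox2. Dcn, Postn, Fbn1 and Col1a2 stayed past the threshold with total counts alone, at a mean log2 fold change of 0.89 ± 0.33 (SD over genes). That setting kept 92.1% of all calls, and with TMM the mean of these genes was 0.86. The choice between TMM and total counts is therefore argued against as the cause. A scaling error shared by both was not tested. Expression by the placode cells themselves remains a hypothesis, and reads shared with paralogs were not tested. Dcn and Col1a2 overlap 0 other genes of the table, which argues against reads from overlapping genes for these 2, whereas Fbn1 overlaps Gm9913 and Postn was not examined.

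Melanoblast markers were lower in the placode-enriched cells in 7 of 7 pairs. A candidate explanation is melanoblasts among the MAdCAM-1 negative cells, which a sort on that protein and on live cells would not remove. Over the 7 IFE libraries the 9 tested markers varied together, with a mean pairwise correlation of 0.54 against a median of -0.02 in 1000 expression-matched random lists, above 100% of them. Kit, at 50.1 CPM, and Sox10, at 30.1 CPM, were the most abundant in IFE libraries. That pattern is consistent with a shared cell source, but a difference in the epithelial cells of the fractions themselves was not tested and stays open.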

How the results depend on the processing

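The settings with structural noncoding RNA were chosen only after the results were seen. Of the genes called with the pair block, 0 changed sign under any alternative. The count of 4786 was 4689 with no replicate block, of which 4434 (92.6% of the 4786) were the same genes. With a pair left out it was 3953 to 5229. It was 4575 with library size only, 5400 with DESeq2, and 4716 with the structural RNA covariate, of which 4040 (84.4% of the 4786) were the same genes. Each set of pairs alone gave fewer genes, 2331 (1226 higher, 1105 lower) in the 3 pairs starting with 27-7 and 3087 (1547 higher, 1540 lower) in the 4 others. Of 127 named genes, 13 lost their call in the 3 pairs and 7 in the 4 pairs, without the pair block Krt14 did (0.0851), and with the covariate Krt14 (0.0832) and Piezo2 (0.061) did. Values that were near 0 turned sign in the 3 pairs, Axin2 to 0.004, Mki67 to -0.008 and mt-Nd6 to 0.062, and Axin2 was at 0.002 with the covariate. None of these had passed.

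Among the lists, adjusted p-values were 0.0754 for the Wnt/beta-catenin targets with an estimated correlation, and 0.0116 for S phase and 0.0359 for G2 and M phase with fry, which called 24 lists against 12. The G2 and M phase list lay between 0.0186 without replicate 5 and 0.188 without replicate 3. Directions of lists far from the threshold turned: actomyosin with fry (0.966), no replicate block (0.826), library size only (0.995), the stricter filter (0.937); basal epidermis with no block (0.983); myeloid cells with no block (0.983) and library size only (0.995). With a pair left out these lists lay between 0.873 and 0.996 (actomyosin), 0.806 and 0.996 (basal epidermis), 0.865 and 0.989 (myeloid cells) and 0.677 and 0.98 (mitochondrially encoded genes), and the direction of each turned at least once. The block changed the calls of the lists for Wnt ligands (0.0325), cholesterol synthesis (0.0485) and Schwann cells (0.0262), and no other list. The myeloid sum turned to 0.02 with raw library sizes, and DESeq2 called 1 gene for the title code. The cause was not tested for these changes.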

Other observations

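The gene families and the list of imprinted genes were chosen only after the results were seen.

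Gene families defined by a shared symbol root, with 8 or more tested members, were compared as groups. Of 235 families, 11 passed (camera, adjusted p under the 0.05 threshold), and 0 of these passed with an estimated correlation. The Sema, Krt, Trp, Atp, Sox and Arhgef roots were among the 11 and are not described further. Sema, all of whose members are in the guidance list, had the smallest camera adjusted p (3.76e-06, or 0.21 with an estimated correlation). Among 14 tetraspanins, 7 were higher, 4 lower and 3 did not pass (adjusted p = 0.0195; adjusted p = 0.685 with an estimated correlation), with Tspan18 at 50.5 against 3.01 CPM (log2 4.09 ± 0.11) and Tspan5 at 1.45 ± 0.09. Among 8 galectins and related genes, 4 were lower and 4 did not pass (adjusted p = 0.0417; adjusted p = 0.685 with an estimated correlation), with Lgals3 at 1.73 against 26.4 CPM (-3.99 ± 0.18). Among 14 phospholipase A2 and related genes, 7 were lower, 1 higher and 6 did not pass (adjusted p = 0.0417; adjusted p = 0.685 with an estimated correlation), with Pla2g2f at 3.41 against 39.9 CPM (-3.62 ± 0.21). Among 15 Serpinb protease inhibitor genes, 8 were lower, 4 of them near-identical neighbours whose values are uncertain, 5 higher and 2 did not pass (adjusted p = 0.0417; adjusted p = 0.775 with an estimated correlation).

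Among 8 voltage-gated calcium channel genes, 3 were higher and 5 did not pass (adjusted p = 0.0417; adjusted p = 0.685 with an estimated correlation), namely Cacna1e (4.86 ± 0.40), Cacna1h (2.28 ± 0.16) and Cacna1g (1.16 ± 0.15). The directions of these families were the same under the 4 scalings tried.

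The imprinted growth regulators Plagl1 (-2.25 ± 0.08), Igf2 (-1.26 ± 0.14), H19 (-0.99 ± 0.09) and Cdkn1c (-0.54 ± 0.07) were lower in the placode-enriched cells in 7 of 7 pairs. If imprinted genes as a class were lower, the others should follow, but of 26 other imprinted genes 3 were higher, 4 lower and 19 did not pass (median -0.15; camera adjusted p = 0.772, over this 1 list), so a shift of the class cannot be told apart from none. Nnat (1.80 ± 0.11) and Ndn (1.18 ± 0.16) were among those higher. A larger share of suprabasal cells in the IFE fraction could also lower these genes in the other fraction. Over the 7 IFE libraries their mean rose with that of the suprabasal list with Pearson r = 0.58 (exact permutation p = 0.172) and a Spearman correlation of 0.64 (exact permutation p = 0.139), and r was 0.36 without the 2 farthest libraries, so 7 libraries are too few to decide.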
